A study of Homo sapiens with 4 samples.

How the data were processed

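H3K27ac was profiled by CUT&Tag in 4 samples of Kasumi-1 cells, 2 with a non-targeting guide (sgNT) and 2 with a guide against SETD8 (sgSETD8), grouped by the sample titles. Per the labels, 100000 cells entered each library and a commercial CUT&Tag kit was used. The series design text names another mark, H3K27me1, while all sample titles and antibody labels name H3K27ac, which is used here. Adapters were trimmed with cutadapt and reads aligned with Bowtie2 to hg38, per the submitters' processing notes, which give no versions. The peak caller, the stitching of peaks and the annotation tool are not given in the sources used here.

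The deposited data are 4 tables of enhancer regions with coordinates, an identifier that counts the stitched peaks, a gene annotation and 1 value column. That column is a signal as deposited by the authors, a density of at most 4 decimals per bp multiplied by the region's length, and what the density is scaled to is not stated. Each table was assigned to a group from the guide named in its region identifiers. Tables whose identifiers share a naming scheme were taken as a pair, giving a sparse and a dense pair. In the sparse pair the identifiers of the table read as sgNT name only the cell line, so its group rests on the absence of a SETD8 guide name. Which of the 2 samples of a group a table belongs to was not resolved. The number of value columns left without a group was 0. Few regions of any table lie wholly within 2500 bp of a TSS, so narrow promoter peaks were hardly covered. The tables hold no read counts, so the depth per sample is unknown and no value has a depth-based error.

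Regions on chromosomes 1 to 22, X and Y were used. Overlaps were computed with bedtools 2.31.1 at a minimum of 1 bp, and set beside 100 seeded random placements of the other table on the same chromosomes. The Jaccard index divided bases covered in both sets by bases covered in either. Shares have exact Clopper-Pearson 95% intervals, which treat regions as independent and cover counting only. Genes are those of the deposited annotation, whose TSS positions lay inside the named gene's span in a GRCh38 gene table for 99.6% to 99.9% of the checked regions of a table. Super-enhancers were computed here, as regions past the point where the scaled curve of ranked signal has slope 1, and are not the authors' calls. Apart from these and the comparison of signal density at matched regions, the authors' signal was used only to rank regions within a table. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

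The samples, tests, 20 gene lists, rule for named genes and main alternatives were fixed before the data were examined. The lists cover oxidative phosphorylation subunits, mitochondrial dynamics, mitophagy, mitochondrial biogenesis and mtDNA expression, the TCA cycle, antioxidant defence, p53 targets, cell cycle and mitosis, the LSC17 stemness score, t(8;21) core factors and targets, haematopoietic stem and progenitor genes, myeloid differentiation genes, apoptosis regulators, H4K20 and H3K27 modifying enzymes and readers, and SWI/SNF remodelling, with erythroid and megakaryocyte, B cell, T and NK cell and non-haematopoietic markers and housekeeping genes as controls. Some genes are in more than 1 list. For each list the difference in mean number of regions per gene, sgSETD8 minus sgNT, was placed among 10000 random lists of the same size matched on the gene's total regions over both groups, drawn from 20054 genes with seed 20. The percentile describes these tables and is not a p-value. Named genes were KMT5A, RUNX1 and RUNX1T1, the genes of the 10 best-ranked regions of each table, the genes of the 10 best-ranked regions absent from the other group, and up to 4 members of each list. List members were taken first if they had a region in 1 group only and then by the difference in number of regions. Names made of an accession or with a LOC, LINC or MIR prefix were passed over. Some genes that the rule takes are not reported here.

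Alternatives were a 50% minimum cover, a gap of up to 1000 bp, the best-ranked 5000 regions, the better-ranked part of each table, merging within 12500 bp, leaving out promoter regions, a minimum width of 500 bp, genes with a TSS within 50000 bp, all sequences, and leaving out each pair. The alternatives that kept only regions found in the other pair, left out arms 2p, 9q and 17q, or counted constituent peaks were chosen after seeing the data. So were the merging of neighbouring regions for gene lists, done within a gene, and for super-enhancers, done with summed signal, and the lists without MYB, ARID1B or GPX1. The comparison of signal density was also added then. It used dense regions of both groups that cover each other by at least 90%, and subtracted the median log2 ratio of -0.26. The 10 highest and 10 lowest genes were taken from matched regions among the best-ranked 5000 of both tables. Chromosome arms were split at the middle of the widest gene-free stretch of the gene table, and arm medians are given for at least 20 matched regions.

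The overlap, list and arm computations were tested on simulated data. Of 2000 simulated dense regions, the 600 placed outside the other set were the 600 called absent. Of 100 simulated dense lists of 30 genes, with the difference of every member raised by a whole region, 92 lay beyond the random range, against 3 of 100 unchanged lists, over 20052 genes. Smaller differences were not simulated, so the power to find them is unknown. With a log2 shift of -0.3 planted on 3 arms among 1800 simulated matched dense regions, those 3 arms had the lowest medians, between -0.30 and -0.24. Copy number, sequence content and input DNA were not analysed here.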

Results

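Kasumi-1 is a human acute myeloid leukaemia line that carries the t(8;21) translocation, which fuses RUNX1 to RUNX1T1. Its cells received CRISPR/Cas9 with a non-targeting guide (sgNT, 2 samples) or a guide against SETD8 (sgSETD8, 2 samples). SETD8, whose gene symbol is KMT5A, is the methyltransferase that places the first methyl group on lysine 20 of histone H4. Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active enhancers and promoters, was profiled by CUT&Tag, in which an antibody directs a transposase to the marked chromatin. Each of the 4 deposited tables lists enhancer regions on hg38 with the authors' signal, and 2 tables belong to each group. The tables fall into 2 pairs by the names inside their region identifiers. The pair with few, short regions is called the sparse pair here (5186 sgNT and 7276 sgSETD8 regions), and the pair with many, long regions the dense pair (15149 and 18061). Read depth was unknown, since the tables hold no counts, and no replicate error exists within a pair. Nothing in the labels says that the samples came from separate cultures. A comparison of 2 tables against 2 cannot give an exact two-sided permutation p under 0.333, so no p-values are given, and exact (Clopper-Pearson) binomial intervals cover the counting of regions only.

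The targeted gene and both partners of the fusion were looked at first. KMT5A had an intronic acetylated region in both dense tables, at chromosome 12, 123391880 to 123405087 in sgNT (4 peaks, authors' signal density 0.521 per bp, rank 3224) and 123391713 to 123404801 in sgSETD8 (3 peaks, density 0.475, rank 3326). The scaling of the density is not stated. Relative to the median of matched dense regions, the log2 density at KMT5A was higher with sgSETD8 by 0.13, within the SD of 0.24 over those regions. Neither sparse table held a KMT5A region, and H3K27ac does not show whether the SETD8 protein was lost. RUNX1, the transcription factor that starts the definitive blood programme, had 28 sgNT and 29 sgSETD8 regions in the dense pair, covering 99.0 and 112 kb. Its best-ranked dense region lay at chromosome 21, 34880060 to 34898704, rank 573 in sgNT, and 34880225 to 34899713, rank 445 in sgSETD8. The sparse pair had 4 sgNT and 2 sgSETD8 regions for RUNX1, covering 3.71 and 5.58 kb. RUNX1T1, the corepressor that the fusion joins to RUNX1, had 1 region in each dense table, 10.1 kb in sgNT (chromosome 8, 92021178 to 92031310) and 20.5 kb in sgSETD8 (92014506 to 92035016), both intronic. These regions held 4 and 5 peaks, and the wider one had the lower density, 0.652 per bp in sgNT and 0.433 in sgSETD8. The sparse tables gave it 0 sgNT and 2 sgSETD8 regions, the better-ranked at an exon (chromosome 8, 92014539 to 92015012).

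The next comparison asked how many enhancer regions each group had and how wide they were. In both pairs the sgSETD8 table held more regions, 1.40 times as many in the sparse and 1.19 times in the dense pair, a mean log2 ratio of 0.37 ± 0.17 (SD, n = 2 pairs). The group means were 10168 ± 7045 regions for sgNT and 12669 ± 7626 for sgSETD8 (SD, n = 2), so the gap between groups was smaller than the spread between tables of a group. Median width was 512 bp in sgNT against 341 bp in sgSETD8 in the sparse pair, and 1515 against 1499 bp in the dense pair. Covered length was 7.75 against 6.89 Mb and 133 against 153 Mb. Peaks inside the regions numbered 6026 and 8029 in the sparse pair and 41194 and 46085 in the dense pair. Peak numbers inside the region identifiers ran up to 15260 in sparse sgNT and 11223 in sparse sgSETD8, and to 53417 and 58038 in the dense pair. Of the sparse sgSETD8 regions 29.7% had the shortest width in their table, against 10.9% in sparse sgNT. Among regions of at least 500 bp the log2 ratio in the sparse pair turned to -0.70, and was 0.28 in the dense pair. Some dense regions, 2040 in sgNT (13.5%) and 2576 in sgSETD8 (14.3%), lay within the stitching distance of a neighbour, in 144 and 170 runs, against 0 in the sparse pair. The number of regions of a gene in the dense pair thus depends partly on whether its peaks were joined.

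Regions of 1 group with no overlapping region in the other were compared next. In the dense pair 6143 sgSETD8 regions (34.0%, interval 33.3 to 34.7) had no sgNT counterpart and 3442 sgNT regions (22.7%, 22.1 to 23.4) no sgSETD8 counterpart. The best-ranked dense sgSETD8 regions without a counterpart lay at JMJD1C-AS1 (chromosome 10, 63463054 to 63467952, exon, centred 274 bp from its TSS, rank 1145), C6orf62 (chromosome 6, 24716051 to 24722042, 5' UTR, centred 108 bp from its TSS, rank 1486) and MYO10, a myosin of filopodia (chromosome 5, 16828675 to 16854074, intron, rank 1716). USP16, PSMB1, TATDN1, AKAP13, SMARCD2, STAMBPL1 and GMNN followed, among them the proteasome subunit PSMB1 (chromosome 6, 170549412 to 170555881, intron), the SWI/SNF subunit SMARCD2 (chromosome 17, 63837498 to 63844700, intron) and GMNN, the inhibitor of replication licensing (chromosome 6, 24773391 to 24793294, intron). The best-ranked dense sgNT regions without a counterpart lay at C6orf223 (chromosome 6, 43966946 to 44007132, intergenic, rank 940), MYCBPAP (chromosome 17, 50502880 to 50535366, intron, rank 1492) and ERN1, which encodes the endoplasmic reticulum stress sensor IRE1 alpha (chromosome 17, 64083718 to 64121323, intron, rank 1669). NACAD, LIAS, RUVBL1, SPDEF, RASGEF1A, HMMR and MESP1 followed. For LIAS, the enzyme that makes lipoic acid in mitochondria, the nearest sgSETD8 region was 20 bp away, for ERN1 it was 230 bp away, and for USP16 the nearest sgNT region was 691 bp away, while for MYO10 it was 264504 bp away. With regions merged across the stitching distance, 9 of the 20 named dense regions still had no counterpart.

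In the sparse pair most regions had no counterpart, 6193 in sgSETD8 (85.1%, interval 84.3 to 85.9) and 4104 in sgNT (79.1%, 78.0 to 80.2). The best-ranked sparse sgSETD8 regions of this kind lay at KLF6, a zinc finger transcription factor (chromosome 10, 3782565 to 3803060, intergenic, rank 3), and IRF2BP2, a transcriptional corepressor (chromosome 1, 234606048 to 234612291, exon, rank 12). MALAT1, CLIC1, LPCAT1, IGFBP2, FOXO3, DNAJB6, CD69 and AFAP1-AS1 followed. Of these 10, the regions of KLF6, IRF2BP2, MALAT1, CLIC1, FOXO3, DNAJB6 and CD69 overlapped regions of both dense tables, and those of LPCAT1, IGFBP2 and AFAP1-AS1 overlapped neither. The best-ranked sparse sgNT regions without a counterpart included those of PCBD2, CD69, CMTM7, ESPNP, RUNX1, RIN3, SH3BGRL3 and AHNAK. PCBD2 (chromosome 5, 134925246 to 134925742, intron, density 92.3) and ESPNP overlapped no dense region, and the others named here overlapped both dense tables. With 100 random placements of the other table on the same chromosomes, 91.7% of dense sgSETD8, 90.3% of dense sgNT, 99.6% of sparse sgSETD8 and 99.4% of sparse sgNT regions had no counterpart. The share of bases covered in both groups out of those covered in either (the Jaccard index) was 55.8% in the dense and 8.04% in the sparse pair. Between tables of the same group it was 4.26% for sgNT and 1.45% for sgSETD8, where the small covered length of the sparse tables limits it. Of the sparse sgNT regions 71.2% overlapped the dense sgNT and 74.5% the dense sgSETD8 table, against 20.9% for the sparse sgSETD8 table. Random placement of those tables gave 5.31%, 6.01% and 0.61%. Of the sparse sgSETD8 regions 24.7% and 26.3% overlapped the dense sgNT and sgSETD8 tables, against 14.9% for the sparse sgNT table. Here random placement gave 5.02%, 5.80% and 0.44%. The dense tables cover far more bases, so these shares do not rank the agreement between tables.

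**Figure D1:**
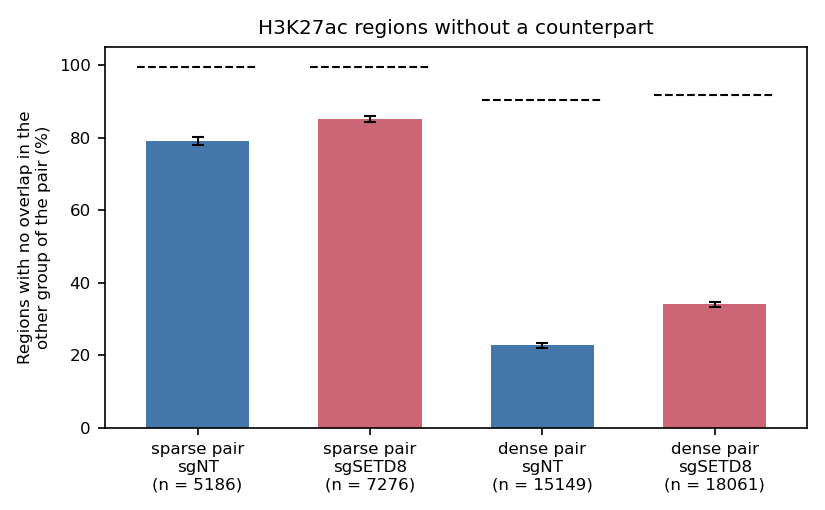
Share of H3K27ac regions (percent, bars) with no overlap of at least 1 bp in the other group of the same pair, with exact 95% binomial intervals for counting; dashed lines give the mean of 100 random placements. All 4 shares lie below their random placement, between 22.7% for dense sgNT and 85.1% for sparse sgSETD8.

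The sparse sgSETD8 regions without a counterpart were unevenly spread over the genome. Chromosome arm 5p, which holds LPCAT1, MYO10 and IL7R, held 413 of them, 6.67% of the total, against 51 sgNT regions without a counterpart, while 5q held 184 against 154. Arms 4p (213 against 63), 8q (312 against 100) and 6q (286 against 107) also held more in sgSETD8. Arm 17q, where ERN1 lies, held 257 in sgNT against 195 in sgSETD8. Of the 413 regions on 5p, 30 (7.26%, interval 4.95 to 10.2) overlapped a dense region of either group. In the dense pair 17q held 245 sgNT and 163 sgSETD8 regions without a counterpart, and 5p 23 and 88.

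**Figure D2:**
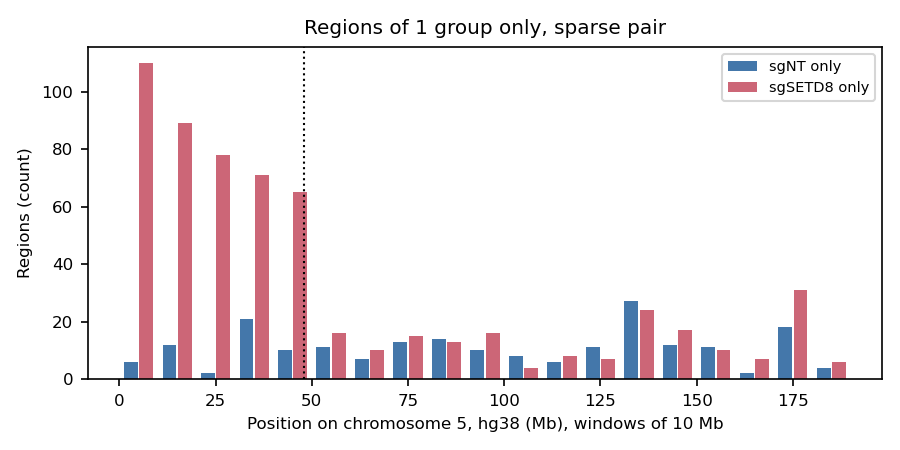
Number of regions found in 1 group only in the sparse pair, per window of 10 Mb along chromosome 5 (position on hg38), for sgNT (blue) and sgSETD8 (red); the dotted line marks the boundary between the arms. The first window of the short arm holds 110 sgSETD8-only and 6 sgNT-only regions.

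The deposited annotation was used to ask where the regions lie. Most dense regions were intronic, like those of TRIO, GNAQ and JARID2, with 68.3% in sgNT and 67.5% in sgSETD8, and intergenic sequence held 24.5% and 25.4%. In the sparse pair intergenic regions made up 37.1% of sgNT and 46.9% of sgSETD8 regions, and introns 56.1% and 47.3%. The intergenic share was therefore 9.83 percentage points higher with sgSETD8 in the sparse and 0.84 points in the dense pair, a mean of 5.33 ± 6.36 (SD, n = 2 pairs). Among sparse regions that overlapped a dense region the difference was -4.07 points. Sparse sgSETD8 regions without a counterpart were intergenic in 48.2% against 39.6% of those with one, and dense ones in 31.4% against 22.2%. For dense sgNT the shares were 30.5% and 22.8%, but for sparse sgNT they ran the other way, 36.5% and 39.6%. Regions annotated to promoters were at most 1.18% of any table, and 18 to 50 regions of a table lay wholly within 2500 bp of a transcription start site (TSS). Narrow promoter peaks were thus hardly covered by these tables.

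Genes were then compared by whether the deposited annotation assigned them a region. In the sparse pair 4001 genes had a region in sgNT and 5266 in sgSETD8, and in the dense pair 8609 and 9593, ratios of 1.32 and 1.11. Both dense tables held a region for 7376 genes, sgSETD8 alone for 2217 and sgNT alone for 1233. These counts were 1870, 3396 and 2131 in the sparse pair. Across the 4 tables, a total of 376 genes had a region in both sgSETD8 tables and in no sgNT table, and 113 the reverse, while 209 and 169 genes went opposite ways in the 2 pairs. More genes were sgSETD8-only than sgNT-only within each pair, so the gap between 376 and 113 needs no agreement between pairs. Among the listed genes, the cell cycle inhibitor CDKN1A, the replicative helicase subunit MCM6, the myeloid surface protein CD33, the deacetylase SIRT1, the SWI/SNF subunit PHF10 and the ATP synthase subunit gene ATP5MC2 were found with sgSETD8 in both pairs and never with sgNT. They were matched by gene name, not by position, and several ranked low. The best ranks of CD33 were 7229 in sparse and 12480 in dense sgSETD8. In dense sgSETD8, SIRT1, PHF10 and ATP5MC2 ranked 13828, 14062 and 17987, and CDKN1A and MCM6 6639 and 5237. MIEF1, a receptor of the mitochondrial fission machinery, was found with sgNT in both pairs and never with sgSETD8. By position, 135 loci were covered in both sgSETD8 tables only and 132 in both sgNT tables only, of 26264 loci, while 246 were covered in sparse sgNT and dense sgSETD8 only and 80 in sparse sgSETD8 and dense sgNT only. With the best-ranked 5000 regions of each table, the log2 ratios of assigned genes were -0.0097 and 0.00037 in the sparse and dense pair.

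The series title names t(8;21) leukaemia stem cells, and genes tied to that state were grouped first. The t(8;21) core factors and targets had 39 sgNT and 25 sgSETD8 regions in the sparse pair, 12 of 29 members having fewer and 2 more with sgSETD8. This placed the list at percentile 0.690 of 10000 random lists matched on region number. SOX4 and RASSF2 (2 to 0) had fewer and LYL1 (0 to 1) had more, while SOX4 went from 1 to 2 in the dense pair. In the dense pair the list had 93 and 90 regions (percentile 10.1), with the ETS factor gene FLI1 at 12 and 10, the phosphatase gene UBASH3B at 2 and 1, ERG at 4 and 5 and TCF12 at 6 and 5. With neighbouring regions of a gene merged across the stitching distance, a setting chosen after the results were seen, the dense list went from 57 to 52 (9 members fewer, 4 more) and lay below the range as well (percentile 0.900). Haematopoietic stem and progenitor genes went from 42 to 27 regions in the sparse pair (9 members fewer, 3 more, percentile 0.770) and from 98 to 94 in the dense pair (percentile 8.43). MYB decided the dense direction, with 13 sgNT regions, most of them unjoined neighbours, against 3 sgSETD8 regions. Without MYB the dense list went from 85 to 91 regions, inside the central 95%. The chemokine receptor gene CXCR4 went from 3 to 0 in the sparse and from 4 to 5 in the dense pair, and BCL11B and PROM1 from 0 to 1 in the sparse pair. In the dense pair IKZF2 went from 2 to 0, HOXA10 from 0 to 2, and HOXA9 from 0 to 1. Among sparse regions that overlapped a dense region, the percentiles were 7.21 for the t(8;21) list (35 to 14 regions) and 11.3 for the stem and progenitor list (36 to 18), inside the central 95% of random lists. Both also lay inside it within 50000 bp of the TSS (4.46 and 20.9) and when constituent peaks were counted (23.3 with 43 to 38 peaks, and 15.1 with 49 to 41).

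The LSC17 stemness score stood at percentile 13.4 in the sparse and 70.9 in the dense pair. CD34, the surface marker of progenitors, had 3 and 2 sparse regions, SMIM24 2 and 0, and CDK6 4 and 2, while in the dense pair CDK6 went from 1 to 3, ZBTB46 went from 0 to 2, MMRN1 and EMP1 from 0 to 1, and ADGRG1 from 1 to 0. Myeloid differentiation genes stood at 38.4 and 22.7. CSF3R, the receptor of granulocyte growth factor, had 0 and 3 sparse regions, and VCAN (2 and 0), CEBPA and CSF1R (1 and 0) had fewer with sgSETD8. In the dense pair the granule genes CAMP and LTF went from 1 to 0, and CD33 and FCER1G from 0 to 1.

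Mitochondrial genes were grouped because the series title names mitochondrial homeostasis. Oxidative phosphorylation subunits stood at percentile 36.5 in the sparse and 19.6 in the dense pair, where ATP5MG, ATP5F1A and NDUFB9 went from 1 to 0 regions and COX4I1 from 0 to 1. Mitochondrial dynamics genes stood at 12.3 and 57.6. The fusion protein gene MFN2 went from 0 to 2 in the dense pair, PHB2 from 0 to 1, and INF2 and MIEF1 from 1 to 0. Mitophagy genes stood at 44.6 and 77.4, with the kinase gene ULK1 going from 1 to 0 and CALCOCO2 and MAP1LC3B from 0 to 1 in the dense pair. Mitochondrial biogenesis and mtDNA expression genes stood at 87.1 and 23.5. PPARGC1A, the coactivator that drives mitochondrial biogenesis, had 2 sgNT and 7 sgSETD8 regions in the sparse and 1 and 4 in the dense pair, while the mtDNA packaging factor gene TFAM, GFM1 and HSPE1 went from 1 to 0 in the dense pair. PPARGC1A lies on arm 4p, where sgSETD8-only regions outnumbered sgNT-only ones in both pairs (213 against 63 sparse, 115 against 44 dense). TCA cycle genes stood at 42.7 and 55.0, with PDHA1 going from 0 to 2, MDH1 from 0 to 1, and PC and IDH3A from 1 to 0 in the dense pair. The sparse pair showed IDH3A at 0 and 1. All these percentiles lay inside the central 95% of random lists.

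Antioxidant defence genes stood at percentile 32.5 in the sparse and 96.6 in the dense pair, where they had 25 sgNT and 39 sgSETD8 regions and 10 of 26 members had more with sgSETD8 against 1 with fewer. The glutathione peroxidase gene GPX1 went from 0 to 6 regions, NQO1 and SOD2 from 0 to 1, and SRXN1 from 1 to 0. Counted as constituent peaks the dense list had 82 in both groups (percentile 21.6), while within 50000 bp of the TSS it stood at 99.5. Without GPX1 the dense list went from 25 to 33 regions (percentile 76.9). The p53 targets stood at 73.0 and 56.0. CDKN1A went from 0 to 1 region in the sparse and from 0 to 2 in the dense pair, CCNG1, TNFRSF10B and POLH from 0 to 1 in the dense pair, and BBC3 from 0 to 1 in the sparse pair. Cell cycle and mitosis genes stood at 27.4 and 49.6. The licensing factor gene CDT1 went from 3 to 0 in the dense but from 0 to 1 in the sparse pair, MCM6 and TOP2A went from 0 to 1 and E2F2 from 1 to 0 in the dense pair, and TOP2A from 1 to 0 in the sparse pair. Apoptosis regulators stood at 5.70 and 44.4, with BIRC2 going from 2 to 0, BIRC3 from 0 to 1 and BCL2L2 from 1 to 0 in the dense pair. APAF1, the core of the apoptosome, went from 0 to 2 in the dense and from 1 to 0 in the sparse pair.

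Among chromatin genes, the SWI/SNF remodelling list stood at percentile 0.365 in the sparse pair, from 14 to 5 regions (7 members fewer, 2 more), and at 92.9 in the dense pair, from 24 to 36 (9 more, 2 fewer). The pairs thus went opposite ways. SMARCC1 and SMARCA4 (2 to 0) and ARID1A and BCL7A (1 to 0) had fewer sparse regions with sgSETD8. In the dense pair SMARCC1 went from 2 to 3, SMARCD2 and PHF10 went from 0 to 3, and BRD7 and SMARCC2 from 1 to 0. The sparse list stood at 23.8 among regions that overlapped a dense region and at 8.56 within 50000 bp of the TSS, inside the central 95%. Counted as constituent peaks the dense list went from 86 to 174 (percentile 99.97), mostly through ARID1B (29 to 96). Its best-ranked sgSETD8 region held 86 peaks, and the sgNT regions over the same span held 83, of which 62 were assigned to a microRNA gene. Without ARID1B the dense list went from 57 to 78 peaks (percentile 90.2), inside the central 95%. H4K20 and H3K27 modifying enzymes and readers stood at 14.0 and 69.6, with HDAC3 and SIRT1 going from 0 to 2, KAT8 from 0 to 1, KAT7 from 2 to 0 and HDAC9 from 3 to 10 in the dense pair, while HDAC9 went from 3 to 0 in the sparse pair. With the best-ranked 5000 regions the dense percentile was 99.1.

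Markers of other cell types and housekeeping genes served as controls. Erythroid and megakaryocyte markers stood at percentile 53.9 in the sparse and 36.0 in the dense pair, where the factor gene NFE2 went from 1 to 4 regions and GP1BB from 1 to 0. B cell markers stood at 57.4 and 61.2, with BANK1 going from 1 to 3, CD79A and BLNK from 0 to 1 and IGLL1 from 1 to 0 in the dense pair. T and NK cell markers stood at 58.3 and 74.1. IL7R, the interleukin-7 receptor gene, went from 0 to 2 in the sparse and from 3 to 6 in the dense pair, and ZAP70 from 3 to 4 and CD8A from 1 to 2 in the dense pair, while ZAP70 went from 1 to 0 in the sparse pair. IL7R lies on arm 5p, where sgSETD8-only regions outnumbered sgNT-only ones in both pairs (413 against 51 sparse, 88 against 23 dense). Non-haematopoietic markers stood at 72.6 and 70.1, and the sparse percentile was 98.9 within 50000 bp of the TSS. CDH5 went from 1 to 3, KDR from 3 to 4, EPCAM from 0 to 1 and TTR from 1 to 0 in the dense pair. Housekeeping genes stood at 36.4 and 9.69, with ENO1 and EEF2 going from 1 to 0 and B2M and HPRT1 from 0 to 1 in the dense pair. Of the 20 lists 3 lay outside the central 95% of random lists in the sparse pair, 0 in the dense pair and 0 the same way in both. With neighbouring regions of a gene merged, 1 list, that of t(8;21), lay outside the same way in both.

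**Figure D3:**
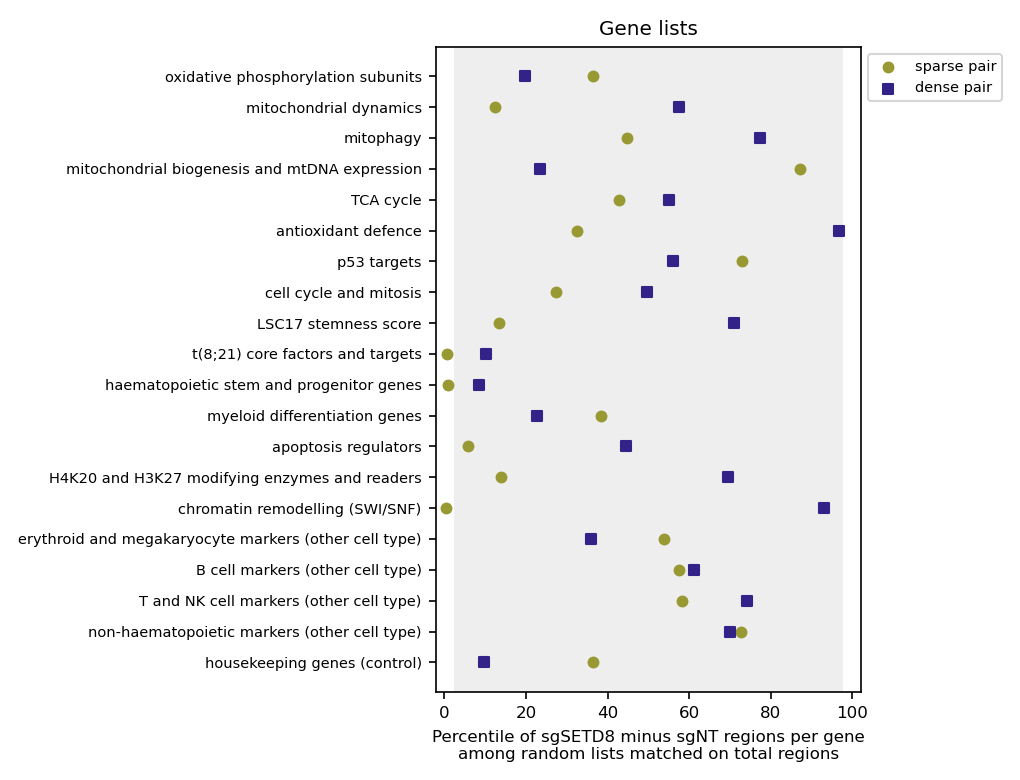
Percentile of each of the 20 gene lists, by the sgSETD8 minus sgNT number of regions per gene, among 10000 random lists matched on total regions; olive circles show the sparse pair, blue squares the dense pair and the grey band the central 95% of random lists. The t(8;21), stem and progenitor, and SWI/SNF lists lie below the band in the sparse pair only.

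The strongest enhancers of each table were compared as super-enhancers, taken here as the regions past the point of slope 1 on the ranked signal curve. TRIO, a guanine nucleotide exchange factor, held the best-ranked region of both dense tables (chromosome 5, 14143867 to 14305702 in sgNT, intron). KIT, the receptor of stem cell factor, ranked 5 in sgNT and 3 in sgSETD8 (chromosome 4, 54653503 to 54723699 in sgNT, intron). JARID2, FNDC3B, RREB1, GNAQ, CCNY, ZMIZ1 and the survival gene BCL2 (chromosome 18, 63090900 to 63323238 in sgNT) ranked between 2 and 12 in both groups. GALNT18 completed the 10 genes named for sgNT and ARID1B those for sgSETD8. In the sparse pair NEAT1, the RNA scaffold of paraspeckles, ranked 1 in sgNT (chromosome 11, 65403821 to 65436554) and 4 in sgSETD8. FAM133B, FNDC3B, MALAT1, MYO18A, ASB9P1, ZNF267, POPDC2, SETD1B and GNAQ were the other best-ranked sparse sgNT genes, and LAMA3, KLF6, RBPJ, LHFPL3-AS2, TBL1XR1, HECW2-AS1, PRPF40B, ENSA and IRF2BP2 those of sparse sgSETD8.

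The dense tables held 709 super-enhancers in sgNT and 769 in sgSETD8, of which 577 (81.4%, interval 78.3 to 84.2) and 576 (74.9%, 71.7 to 77.9) overlapped a super-enhancer of the other group. All of them overlapped some region of the other group. Of the sparse super-enhancers 75 of 157 (47.8%) and 76 of 204 (37.3%) were shared. Both dense groups had super-enhancers at ERG, KIT, LMO2, RUNX1, SPI1, TCF12 and UBASH3B of the t(8;21) list, at BCL11A, CD34, ETV6 and IKZF1 of the progenitor list, and at ARID1A, ARID1B and ARID2 of the SWI/SNF list. TRIB1, MYB, PMAIP1, WEE1 and TFRC were above the threshold with sgSETD8 only in the dense pair, and DOT1L and TBK1 with sgNT only. Some lay close to it, since TBK1 ranked 704 in sgNT and 918 in sgSETD8, and WEE1 768 in sgNT and 388 in sgSETD8. The sparse pair placed PMAIP1 the other way, above the threshold with sgNT only, together with DOT1L, RUNX1 and JARID2, and LYL1, BCL2, KDR and ACTB with sgSETD8 only. The best-ranked dense super-enhancer without a super-enhancer in the other group lay at GFOD1 in sgNT (chromosome 6, 13334913 to 13494137, rank 15) and at COL14A1 in sgSETD8 (chromosome 8, 119970471 to 120089515, rank 113). The GFOD1 locus was split into many neighbouring regions in sgSETD8, as MYB was in sgNT. With neighbouring regions merged across the stitching distance, 83.4% of dense sgNT and 80.1% of dense sgSETD8 super-enhancers were shared. GFOD1 and MYB were then above the threshold in both groups, while COL14A1, TRIB1, PMAIP1, WEE1, TFRC, DOT1L and TBK1 stayed above it in 1 group only.

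Signal density was compared at dense regions that covered each other by at least 90%, with genes named from those among the best-ranked 5000 of both tables, a comparison added after the tables were examined. Only the change relative to the median of the 1769 matched regions is given, since the scaling of the signal is not stated. Relative log2 density was higher with sgSETD8 at UBE2E2 (0.55), PTPRG (0.54), AGR3 (0.53), NEDD9 (0.53), COMMD8 (0.51), IL7R (0.51), SRSF4 (0.50), MACC1 (0.50) and CCDC26 (0.50). It was lower at TXN, which encodes thioredoxin (-0.70, chromosome 9, 110253710 to 110258874, intron), BCL11A, a repressor of fetal globin genes (-0.68, chromosome 2, 60465782 to 60562205, intron), MPRIP (-0.66), UBE2O (-0.65), CSMD3 (-0.62), SOS1 (-0.61), MAP3K3 (-0.61), RHEX (-0.61), MYCNOS (-0.60) and the tyrosine kinase gene ABL1 (-0.59). The SD over the 1769 regions was 0.24. The sparse pair had 44 such regions, and of the 9 loci matched in both pairs 8 had the same sign, too few to bear on single genes.

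The lower values clustered on whole chromosome arms. Arm medians were -0.40 on 9q (23 regions, with TXN and ABL1), -0.32 on 17q (59 regions, with UBE2O and MAP3K3) and -0.32 on 2p (60 regions, with BCL11A, SOS1 and MYCNOS). The other arms with at least 20 matched regions lay between -0.15 and 0.14. On the 3 arms 90.8% of 142 matched regions were below the genome median, against 46.4% of the 1627 elsewhere, and 60 of the 100 lowest regions lay there. Arm 5p had 16 matched regions, with a median of 0.16, and IL7R was at 0.35 relative to it. The other arms of the same chromosomes had medians of 0.04 (9p), -0.07 (17p) and 0.02 (2q). Relative to their own arm, TXN was at -0.30, BCL11A at -0.36 and ABL1 at -0.19, while CSMD3 (-0.72), RHEX (-0.61), IMPDH1 (-0.47), IRX5 (-0.47) and the TGF-beta signal transducer gene SMAD3 (-0.45) were the lowest of the genes so named on arms with at least 20 matched regions, and NEDD9 (0.53), CORO2A (0.53), COMMD8 (0.52) and AGR3 (0.52) the highest. MPRIP was at -0.59 relative to 17p, which had 13 matched regions.

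**Figure D4:**
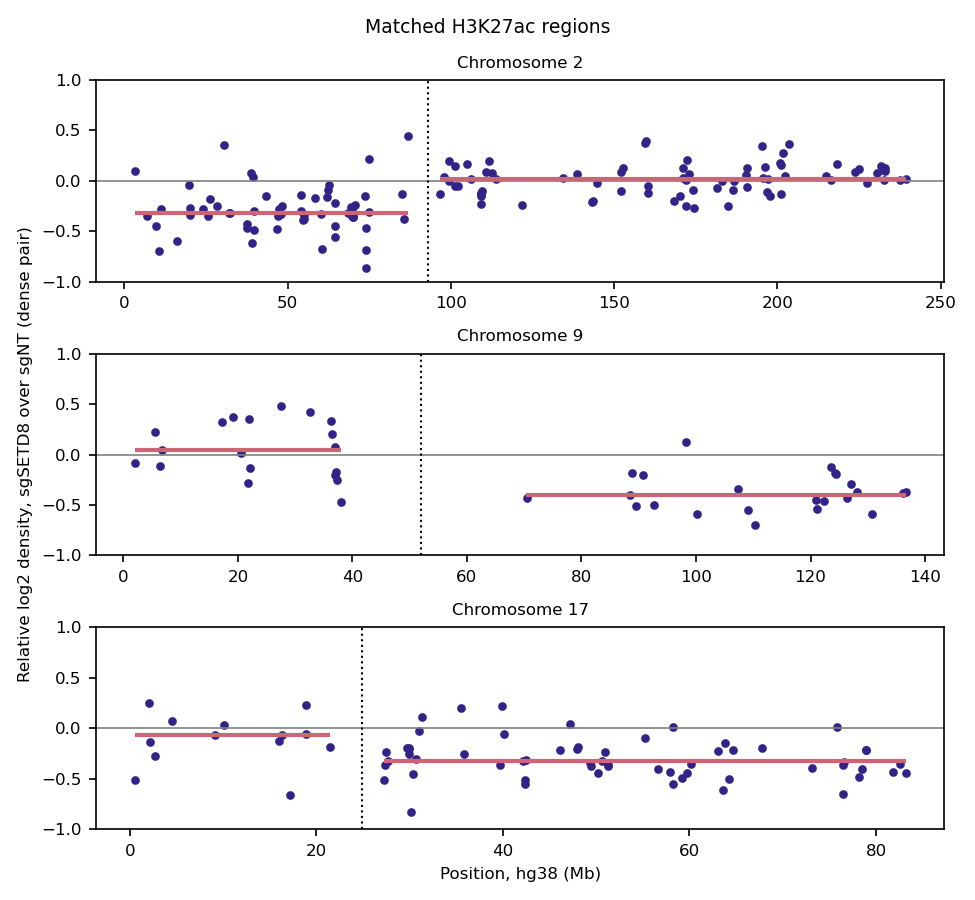
Relative log2 signal density, sgSETD8 over sgNT, of matched H3K27ac regions of the dense pair (points) by position on chromosomes 2, 9 and 17 (hg38, Mb); red lines are arm medians and dotted lines the boundary between the arms. Arms 2p, 9q and 17q have medians of -0.32, -0.40 and -0.32, and the opposite arms 0.02, 0.04 and -0.07.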

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

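All tests in this part were chosen only after the result was seen.

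The deposited tables name the repeat at a region's centre, which no comparison above used, and the sparse sgSETD8 table stood out from its control. LINE elements were at the centre of 19.8% of sparse sgSETD8 regions against 10.2% in sparse sgNT, and LTR elements at 12.5% against 8.43%. Simple repeats were at the centre of 7.53% against 1.06%, and satellites of 0.440% against 0.0964%. The gaps were smaller in the dense pair, with LINE elements at 12.9% in sgNT and 13.9% in sgSETD8, LTR elements at 6.93% and 7.31% and simple repeats at 0.819% and 0.753%.

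The pattern weighed beside these values is the large set of sparse sgSETD8 regions with no sgNT counterpart, such as that at IGFBP2. For the 3.58% of them that overlapped a dense region of 1 group only, the odds of being sgSETD8-only there, relative to sparse sgNT-only regions, were 0.899 (95% interval 0.630 to 1.28). The interval spans 1, so this part shows no direction, and a modest gain on loss of SETD8 stays open for it. The 81.3% that overlapped no dense region were absent from the dense sgSETD8 table as well, although that table covered 153 Mb. This argues against a gain found in both sgSETD8 tables for that part. A gain limited to the sparse sgSETD8 sample stays open for it. Background of a library with lower enrichment also remains open and may account for much of the set, because 18.7% overlapped any dense region, against 75.8% of the sparse sgNT-only regions and 6.66% for random placement. The best-ranked regions named from this set are not like the rest, since most of them, such as those of KLF6, IRF2BP2, MALAT1 and CLIC1, lay in regions of both dense tables.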

How the results depend on the processing

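The settings that kept only regions found in the other pair, left out arms 2p, 9q and 17q, counted constituent peaks, or merged neighbouring regions for lists and super-enhancers were chosen only after the results were seen. No paired analysis was possible because the labels carry no replicate numbers and no table could be assigned to a single sample. The means over pairs of tables rest on the naming scheme of the identifiers and carry no test. Both shares of regions without a counterpart (means over pairs 59.6% and 50.9%), the median width (-0.30), the Jaccard index (31.9%) and the shared super-enhancers (56.1%) moved by less than the SD between pairs under every setting run, which is a weak bound, since that SD spans a sparse and a dense pair (36.1 points for sgSETD8 regions without a counterpart). With both pairs kept, that share ran from 34.5% to 70.0% over the settings. The higher number of sgSETD8 regions (mean log2 ratio 0.37) turned to -0.21 with regions of at least 500 bp (sparse -0.70, dense 0.28) and to -0.42 with only regions found in the other pair (-0.94 and 0.10). The log2 ratio of assigned genes (0.28) turned to -0.0047 with the best-ranked 5000 regions, where table size is equal by construction, and to -0.39 with only regions found in the other pair. The intergenic difference (5.33 points) turned to -1.76 points with only regions found in the other pair. With that setting 0 gene lists lay outside the random range in either pair, against 3. Apart from the equal table size, the cause was not tested. The number of regions, assigned genes and intergenic share kept their direction under the other settings run. The lists outside the range did not stay the same. With constituent peaks only SWI/SNF remained outside in the sparse pair (1.95), and within 50000 bp of the TSS only the non-haematopoietic markers were (98.9). Dense lists passed the range only as t(8;21) with neighbouring regions merged (0.900), SWI/SNF with constituent peaks (99.97, but 90.2 without ARID1B), antioxidant defence within 50000 bp (99.5) and the H4K20 and H3K27 list with the best-ranked 5000 regions (99.1). Without arms 2p, 9q and 17q each of these results kept its direction, with 0.41 for the number of regions and 3 lists.

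Leaving out a pair left the value of the other. The ranges were 34.0% to 85.1% of sgSETD8 and 22.7% to 79.1% of sgNT regions without a counterpart, 0.25 to 0.49 for the number of regions, -0.59 to -0.02 for width, 8.04% to 55.8% for the Jaccard index, 0.16 to 0.40 for assigned genes, 0.84 to 9.83 points for the intergenic share, 37.3% to 74.9% for shared super-enhancers and 0 to 3 lists. Among the named list genes, 341 of 450 alternative values stayed the same, 104 moved and 5 reversed. The reversed differences in number of regions, sgSETD8 minus sgNT, were 1 for CDK6 in the sparse pair and -1 for ERG in the dense pair within 50000 bp of the TSS, and 1 for FLI1, -1 for NFE2 and -1 for CD8A in the dense pair with the best-ranked 5000 regions. Their cause was not tested. Of the named regions without a counterpart, 17 of 20 dense and 20 of 20 sparse ones still had none with a gap of up to 1000 bp allowed, and 9 and 12 with merging across the stitching distance. Read depth is unknown and limits how an absent region can be read, most of all in the sparse pair.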

Other observations

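All tests in this part were chosen only after the result was seen, and so were the genes named from matched regions and from loci covered in both pairs.

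Density at matched dense regions is given for some listed genes, again relative to the median of all matched regions (SD 0.24). Not all listed genes with values of this size are named, and some values, such as that of ETV6, are close to the SD. BCL2A1, an anti-apoptotic BCL2 relative, had a region near it with a relative log2 density of 0.75 (chromosome 15, 79976085 to 79979480), and the cyclin gene CCNE2 one of 0.58. MPO, the myeloperoxidase gene of granulocyte precursors, was at -0.55, and at -0.23 relative to its arm 17q. The mitochondrial protease gene LONP1 was at -0.41, PPARGC1B at -0.28, TAL1 at -0.30 and ETV6 at -0.27, while MYB was at 0.34 and HHEX at 0.33. Among random lists the lowest percentiles rested on few genes, 1.38 for the myeloid list with MPO alone (11.4 relative to its arm) and 1.81 for mitochondrial biogenesis with LONP1 and PPARGC1B (0.550 relative to their arms). Of 7 genes of the H4K20 and H3K27 list 6 were lower, with a median of -0.13 (percentile 8.92).

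Loci covered in both tables of a group and in neither of the other were few. The best-ranked of the 135 sgSETD8 loci lay at the matrix metalloprotease gene MMP7 (chromosome 11, 102537247 to 102561827, intergenic), TAF12 (chromosome 1, 28625009 to 28646308, intron) and IGF2BP2-AS1. The best-ranked of the 132 sgNT loci lay at ERN1, PPP1R27 (chromosome 17, 81829243 to 81841840, promoter) and SPOCK2. Arms 2p, 9q and 17q held 24 of the 132 sgNT loci (18.2%), 6 of the 135 sgSETD8 loci (4.44%, exact interval 1.65 to 9.42) and 97 of the 1175 loci of all 4 tables (8.26%). They held 9 of the 80 loci of sparse sgSETD8 and dense sgNT only (11.25%, 5.28 to 20.3). Of the 246 loci of sparse sgNT and dense sgSETD8 only, they held 12 (4.88%). The share thus went with the dense group, and the arms were chosen by the dense signal, so it does not show an arm difference in both pairs.

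The lower relative density of BCL11A, TXN and MAP3K3 with sgSETD8 goes with the shift of arms 2p, 9q and 17q in the dense pair. Gene density as its source is argued against by chromosome 19, the most gene-dense, whose 38 matched regions had a median of -0.018 (bootstrap interval -0.08 to 0.05). A copy number difference of whole arms between the cells of the 2 groups is a candidate explanation, since the shift ran along each arm, and with each arm split in 3 stretches the highest of the 9 medians was -0.26. An action of SETD8 loss on these arms cannot be told apart from it, because either could give this difference between the groups. Whether the shift recurs in the sparse pair is also unclear, since the interval there spans both signs. The sparse pair gave a median of -0.25 from 27 regions with an interval of -0.76 to 0.16. These 27 are among 435 sparse regions matched with each at least 50% covered. That match is looser than the one used for the dense arm medians. DNA input or sequence content was not analysed here, and which group would hold the changed copy number is open. Copy number was not tested for arm 5p either.

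Several well-ranked dense regions without a counterpart, such as those at JMJD1C-AS1, C6orf62, STAMBPL1 and MESP1, sat at a TSS. In both directions such regions were centred within 2500 bp of a TSS more often than shared regions of the same ranks. The shares were 35.3% (interval 26.8 to 44.6) against 12.5% for sgNT and 42.9% (35.6 to 50.4) against 13.2% for sgSETD8. Most of those at a TSS were made of 1 or 2 peaks, 35 of 42 and 70 of 78. Removal of peaks close to a TSS that differed between libraries is a candidate for them. These values cannot decide it, since regions were matched on rank and not on width or peak number. Over all ranks, dense regions without a counterpart were narrower than those with one. Median widths were 505 against 3049 bp in sgNT and 556 against 4058 bp in sgSETD8. A gain of acetylation at TSSs on loss of SETD8 stays open, with an odds ratio of 1.37 for sgSETD8-only against sgNT-only regions and a 95% interval of 0.831 to 2.28 that spans 1.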
